A study of Mus musculus with 9 samples.

How the data were processed

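Total RNA of cultured mouse prostate cancer cells was hybridised to 9 Affymetrix Mouse Gene 2.0 ST arrays, which measure each transcript with a set of short probes (a probe set). The labels give 3 groups. The parental MYCCaP line was grown with dihydrotestosterone, an androgen, and its 3 arrays are labelled technical replicates. The other 6 arrays hold 3 lines from mice that received vehicle and 3 lines from mice that received AZD1208, labelled biological replicates and grown without dihydrotestosterone. Whether each line came from a separate mouse is not given in the sources used here.

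The deposited values are log2 intensities, 1 per probe set and array, between 1.94 and 14.4. Per the submitters' processing notes the tool was oligo, and its version, background correction, normalization and summary method are not given in the sources used here. The median of each array lay between 6.22 and 6.36, and the columns were alike in range without sharing one distribution, so the scale set by the authors was kept. A compressed or shifted scale on 1 array would move many genes of that array together, which is why quantile normalization and centring on the median were among the alternatives. The values carry no detection calls, so no gene was called present or absent, and a dim gene's difference can be understated. The number of arrays limits the precision.

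Probe sets were named through the platform annotation, with symbols checked through Entrez identifiers against a RefSeq table of assembly GRCm38.p6. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed in that annotation and stayed unnamed. Symbols were updated for 0 probe sets, and 193 of those with 1 symbol had an Entrez identifier outside the RefSeq table. Probe sets with several symbols were named for none of them. For the 1082 genes with more than 1 probe set, the one with the highest mean was used, which gave 22180 genes. The 30% of genes with the lowest mean were left out (below 5.81), which left 15526 genes. The sources name no genome build for the array, and no coordinates are given.

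The 3 parental arrays were averaged and counted as 1 sample, because their spread is technical. The 7 samples were fitted per gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term (4 residual degrees of freedom, 3.36 prior degrees of freedom). The lone parental sample adds no spread of its own and is assumed to vary like the lines of the other groups. The comparisons were AZD1208 against vehicle lines, vehicle lines against parental, AZD1208 lines against parental, and the mean of both recurrent groups against parental. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. They measure only the spread between these lines. The comparisons with the parental line share that sample and are not independent, so overlaps between them were not counted.

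Gene lists were written before the data were examined. Of 33 lists, 32 had at least 3 genes after the filter and were tested with limma's camera, two-sided, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists. Of 773 list entries, 712 had a value. Camera with a correlation estimated per list and limma's fry, which tests whether a list moves one way without comparing it with other genes, were run beside it. Camera asks whether a list's genes differ from the other genes on the array.

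The genes named were set by a rule fixed before the data were examined. Pim1, Pim2, Pim3 and Myc are always named. The fifth gene of that group has no probe set named in the annotation used and was not analysed here. For AZD1208 against vehicle and for recurrent against parental, the rule takes the 10 largest rises and the 10 largest falls among genes past the threshold, with places left over filled by the smallest unadjusted p in that direction, passing over predicted, olfactory and small RNA symbols. No gene passed, so all of these places were filled by unadjusted p. For each list described, up to 4 members with the smallest unadjusted p are named. Genes given line by line in the closing section outside this rule were chosen after their values were seen.

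Vehicle and AZD1208 lines carry the same replicate numbers in the labels. No label says that these numbers pair the lines. Deviations from the group means correlated across genes at 0.146 for the lines numbered 1, 0.118 for those numbered 2 and 0.532 for those numbered 3. Vehicle 1 and AZD1208 2, which do not share a number, correlated at 0.264, above the values for the lines numbered 1 and 2. The data therefore do not establish a pairing, and the main fit used none. A fit with the replicate number as a block was run as an alternative.

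The procedure was tested on simulated values for the 15526 genes with 200 changed genes. For AZD1208 against vehicle it recovered 46.3% of 67 genes changed by 1 on the log2 scale, 95.5% of 67 changed by 2 and 100% of 66 changed by 4, with 8 false calls. For recurrent against parental it recovered 13.4%, 86.6% and 98.5% of the same numbers of genes, with 6 false calls. A list shifted by -0.5 was called in both (camera, adjusted p = 4.44e-16 and 4.64e-13), with 0 other lists called. The simulated genes varied independently of each other, while the correlation estimated in the real data was 0.547 for MYC targets. The simulation therefore does not show how often lists of correlated genes are called falsely. The shares of genes recovered hold for 200 changed genes, since the adjusted p of a gene depends on how many others change. In the real data Krt4 (-5.62) and Hp (4.52) did not pass for recurrent lines against parental. A count of 0 genes past the threshold therefore does not show that large changes are absent.

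Alternatives were no filter or a filter of 50%, quantile normalization, centring on the median, an intensity trend or robust eBayes, array quality weights, the mean of a gene's probe sets, every probe set, the parental arrays as 3 samples, only the groups compared, an adjusted p under 0.1, the replicate block, and each line or parental array left out in turn. Centring was added for the gene lists after the data were seen. Plots were drawn with matplotlib 3.10.9.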

Results

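MYCCaP is a mouse prostate cancer cell line from a tumour of a mouse that carries a prostate-specific MYC transgene. AZD1208 is an inhibitor of the PIM kinases, a family of serine/threonine kinases that promote survival and growth. Expression was measured in the parental line, grown with androgen (1 sample, 3 technical arrays), and in lines made from tumours that had come back in castrated mice given vehicle (n = 3) or AZD1208 (n = 3). The median SD of a gene was 0.09 on the log2 scale between the technical arrays, 0.19 between vehicle lines and 0.25 between AZD1208 lines. The first principal component of the 9 arrays held 49.7% of the variance. On it AZD1208 3 (-17.8) and vehicle 3 (-8.39) lay nearer to the parental arrays (-31.7 to -23.3) than AZD1208 2 (44.9) and vehicle 1 (38.8) did. AZD1208 3 also had the narrowest interquartile range of values, 2.87 against 2.98 to 3.12 in the other arrays. Its array quality weight, 0.34, was the lowest of the 7 samples.

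The first comparison asked whether lines from mice given the PIM inhibitor differ from lines of vehicle mice. Il18r1, a subunit of the interleukin-18 receptor, was at 6.38 ± 0.68 (SD, n = 3) in AZD1208 lines and 8.26 ± 0.68 (SD, n = 3) in vehicle lines, which is 3.7-fold lower (log2 difference -1.89, SE 0.43). Amotl1, a member of the angiomotin family of junction proteins, was 1.76-fold lower (-0.81, SE 0.22). Arhgap44 was 1.78-fold lower (-0.83, SE 0.24). Hp, which encodes the haemoglobin-binding plasma protein haptoglobin, was 2.34-fold higher (1.23, SE 0.39). Slpi, a secreted inhibitor of leukocyte proteases, was 1.83-fold higher (0.88, SE 0.33), with a difference of 0.53 without AZD1208 2 and 0.55 with array quality weights. None of these 5 genes passed the adjusted threshold (adjusted p = 1 for each, limma).

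The other genes of smallest unadjusted p with higher values in AZD1208 lines were Tmem54 (0.59), Gprc5b (0.65, or 0.43 without AZD1208 2), Fam149a (0.45), Prickle3 (0.41), Galnt15 (0.59), Ybx2 (0.38), Pomc (0.40) and Trnp1 (0.47), as log2 differences. Those with lower values were Smim22 (-0.66), Ccbe1 (-0.57), Fcamr (-0.66), Mtmr10 (-0.63), Ppm1l (-0.55), Tpmt (-0.47) and Tbx18 (-0.57). All 20 genes had no overlap between the 3 lines of one group and the 3 of the other, with unadjusted p between 0.00281 and 0.036. Pim1 differed by 0.17 (SE 0.26), Pim2 by 0.11 (SE 0.16), Pim3 by -0.17 (SE 0.18) and Myc by -0.04 (SE 0.31), each smaller than its SE. The sign for Pim1 turned with array quality weights (-0.06) and without vehicle 1 (-0.08), and that for Pim2 with array quality weights (-0.006). That for Myc turned with quantile normalization (0.02) and without vehicle 2 (0.19) or AZD1208 1 (0.17), and Myc was at -0.46 with array quality weights. Pim3 was at -0.05 without AZD1208 2.

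Of 15526 genes, 0 passed in either direction (limma), and 81 had an unadjusted p under 0.05, where chance gives 776. Groups did not overlap for 219 genes that were higher and 307 that were lower in AZD1208 lines. Together these were 3.4% of the genes tested, against 10% by chance.

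**Figure D1:**
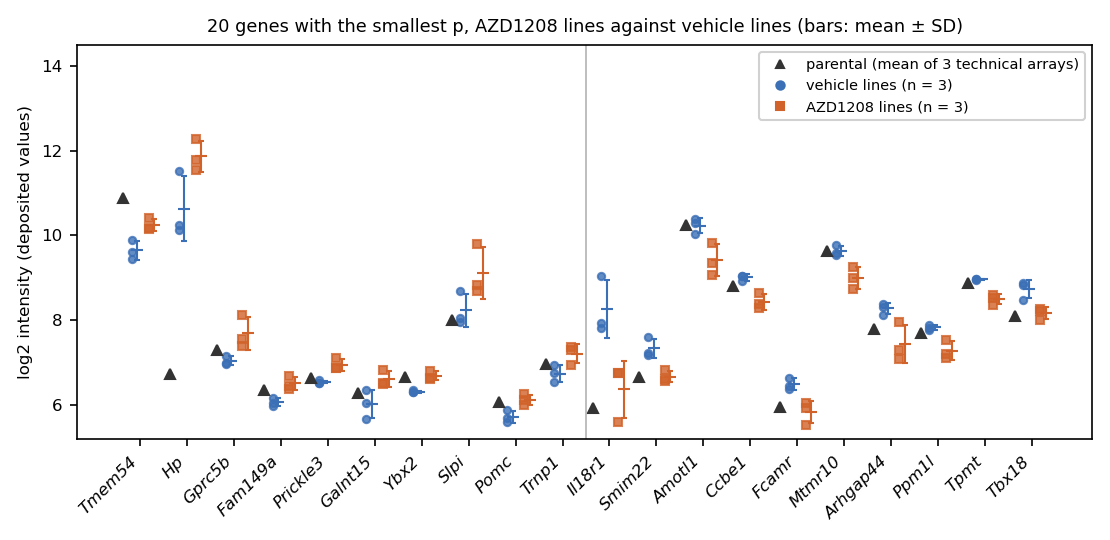
Log2 intensity (vertical axis) of the 20 genes of smallest unadjusted p between AZD1208 and vehicle lines, with higher genes left of the grey line and lower genes right of it; circles are vehicle lines, squares AZD1208 lines, triangles the parental line, and bars the mean ± SD of 3 lines. For Il18r1 the vehicle lines averaged 8.26 and the AZD1208 lines 6.38, with no overlap, and no gene passed the adjusted threshold.

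Among the gene lists, genes of the unfolded protein response fell in AZD1208 lines against vehicle lines, with 20 of 21 members lower and a mean difference of -0.19 on the log2 scale (camera, adjusted p = 0.000278). The call was lost with an estimated correlation (adjusted p = 0.627 with an estimated correlation) and without vehicle 1 (adjusted p = 0.48). In vehicle 1 the list stood 0.47 above the parental line, against 0.16 and 0.09 in the other vehicle lines. Its members of smallest p were Sel1l (-0.23), Ern1, the kinase IRE1 (-0.30), Herpud1 (-0.27) and Hyou1, a chaperone of the endoplasmic reticulum (-0.32), none past the threshold. With single lines left out Ern1 ranged from -0.47 to -0.17 and Hyou1 from -0.49 to -0.15, and Herpud1 was at -0.16 without vehicle 1. Genes of the p53 target list fell, with 18 of 26 lower and a mean of -0.13 (adjusted p = 0.0288; adjusted p = 0.627 with an estimated correlation). They included the cell cycle inhibitor Cdkn1a (-0.52), Perp (-0.37), Zmat3 (-0.36) and Ei24 (-0.33), none past the threshold. With array quality weights Cdkn1a was at -0.27. The estimated correlation was 0.119 for the unfolded protein response but -0.02 for p53 targets, below the preset value. A correlation stronger than the preset therefore does not account for the lost p53 call, and its cause was not tested.

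Neuroendocrine genes rose, with 11 of 17 higher and a mean of 0.12 (adjusted p = 0.015; adjusted p = 0.815 with an estimated correlation). The members of smallest p were the neuronal enolase Eno2 (0.41), Nkx2-1 (0.24), Ddc (0.24) and Neurod1 (0.39), all at mean values under 7, and none passed. Without AZD1208 3 Neurod1 differed by 0.17. Endothelial markers were higher in 10 of 12 genes (mean 0.07, adjusted p = 0.0889) and lymphocyte markers in 6 of 7 (mean 0.10, adjusted p = 0.129), neither list called. Relative to the parental line the neuroendocrine, endothelial and lymphocyte lists were each highest in AZD1208 3 (0.19, 0.13 and 0.22), the array with the narrowest range of values. NF-kB targets rose, with 16 of 22 higher and a mean of 0.15 (adjusted p = 0.0288; adjusted p = 0.815 with an estimated correlation), among them Relb (0.32), Icam1 (0.47), Nfkbie (0.94) and Tnfaip3 (0.69), none past the threshold. Without AZD1208 2 these were 0.15, 0.10, 0.12 and 0.06. With array quality weights Tnfaip3 turned its sign (-0.28), Nfkbie was at 0.27 and Relb at 0.10. Relative to the parental line the NF-kB list stood at 1.26 in AZD1208 2, 0.77 in vehicle 2, 0.23 in AZD1208 3, 0.19 in vehicle 1, 0.08 in vehicle 3 and 0 in AZD1208 1. Without AZD1208 2 its direction turned (adjusted p = 0.396). Fibroblast markers were also highest in AZD1208 2 (1.22), followed by vehicle 1 (0.93), as was the list of epithelial-mesenchymal transition and matrix genes (0.73, followed by 0.37 in vehicle 1).

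These were 4 of 32 lists called, and fry called 0 (smallest adjusted p = 0.628). A two-sided exact permutation test on the lines' list means gave p = 0.2 for the unfolded protein response and p = 0.1 for p53 targets. The same exact permutation test gave p = 0.5 for neuroendocrine genes and p = 0.8 for NF-kB targets. With 3 lines against 3 its smallest possible value is 0.1, so it cannot pass 0.05. The camera calls compare genes with genes and do not establish a difference between the groups of lines. Of the 28 lists not called, the nearest was antigen presentation, with 12 of 14 members higher and a mean of 0.10 (adjusted p = 0.0542). The largest adjusted p was 0.992, for the luminal list. The other calls also depended on single lines, with adjusted p in parentheses. The p53 targets were not called without vehicle 1 (0.151), AZD1208 2 (0.058) or AZD1208 3 (0.289). Neuroendocrine genes were not called without vehicle 2 (0.375) or AZD1208 3 (0.627), nor NF-kB targets without vehicle 1 (0.208) or vehicle 3 (0.409). With the replicate number as a block, 8 lists were called, these 4 among them. The others were MYC targets (down, adjusted p = 0.0464), drug efflux transporters (down, 0.0464), interferon response (up, 0.0402) and antigen presentation (up, 0.0402). In that fit each of the 8 had an adjusted p = 0.815 with an estimated correlation. Only the unfolded protein response was called without the filter on dim genes (adjusted p = 0.00017) and with quantile normalization (0.00635).

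The second comparison set the 6 recurrent lines against the parental line, which differs from them in the androgen in its medium and in not having grown in a castrated mouse. Hp was at 11.25 ± 0.86 (SD, n = 6) in recurrent lines and 6.73 in the parental line, 22.9-fold higher (log2 difference 4.52, SE 0.51). Igfbp5, a secreted binding protein of insulin-like growth factors, was 22.3-fold higher (4.48, SE 0.48). Mxd4, a MAX partner that opposes MYC at its binding sites, was 6.39-fold higher (2.68, SE 0.49). Of the 20 genes named for this comparison, 5 were keratin genes, all with lower values. Krt4 was lower by 49.1-fold (-5.62, SE 1.08), Krt6a by 28.3-fold (-4.82, SE 0.94), Krt79 by 3.44-fold (-1.78, SE 0.26), Krt19 by 2.87-fold (-1.52, SE 0.23) and Krt78 by 2.59-fold (-1.37, SE 0.25). None of these 8 genes passed (limma adjusted p = 0.273 for Hp and Igfbp5, and 0.682 to 1 for the others). Each of the 8 had all 6 lines on one side of the parental value. The other keratin genes tested in the basal and luminal lists were Krt14, Krt18, Krt8 and Krt15, the last 3 named after their values were seen. Krt14 differed by -0.72 (SE 0.23) and Krt18 by -0.23 (SE 0.22), with all 6 lines below the parental values of 7.86 and 6.99. The technical SD of Krt18 between the parental arrays was 0.30. Krt8 differed by 0.07 (SE 0.73) and Krt15 by -0.98 (SE 1.53), with lines on both sides and Krt15 above the parental value of 9.31 in vehicle 1 (10.42) and AZD1208 2 (10.12).

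Higher values were also found for Syne4 (1.83), Antxr1 (1.43), Ndufa1 (1.57), Aldh1l2, a mitochondrial folate enzyme (1.18), Gdpd2 (2.00), Anapc13 (0.94) and Ly6e (1.5), as log2 differences. Lower values were found for S100a7a (-1.95), Elmod1 (-1.18), Bcat1, an enzyme of branched-chain amino acid breakdown (-1.27), Rgs19 (-1.38) and the platelet chemokine Ppbp (-1.95). All 20 genes, which were picked by their p for this comparison, had 6 of 6 lines on one side of the parental value. Of all genes tested 22.6% did, against 28.6% by chance. Myc differed by 0.08 (SE 0.40), with a sign that turned when samples were centred on their median (-0.02) and when vehicle 2 (-0.035) or AZD1208 3 (-0.036) was left out. Whether its probe set also reads the transgene is not known here.

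Of 15526 genes, 0 passed (limma), and 429 had an unadjusted p under 0.05, 313 higher and 116 lower, where chance gives 776. With the parental arrays counted as 3 separate samples, which treats technical spread as if it were biological, 156 genes passed, including all 20 named here. With samples centred on their median Igfbp5 (adjusted p = 0.0277) and Hp (adjusted p = 0.0462) passed.

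**Figure D2:**
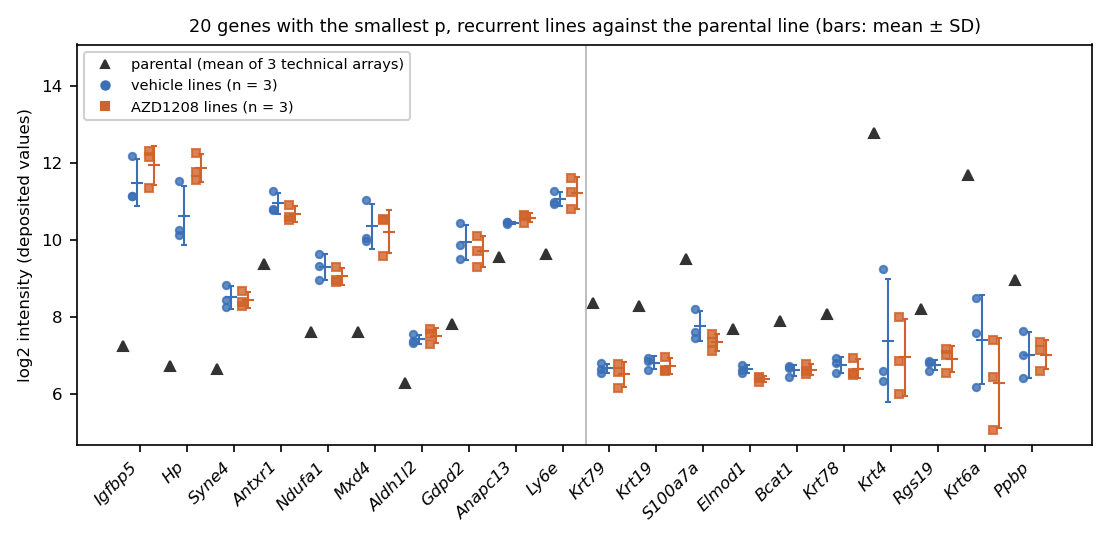
Log2 intensity (vertical axis) of the 20 genes of smallest unadjusted p between recurrent lines and the parental line, with higher genes left of the grey line and lower genes right of it; circles are vehicle lines, squares AZD1208 lines, triangles the parental line, and bars the mean ± SD of 3 lines. All 6 recurrent lines lie above the parental value for Hp and Igfbp5 and below it for Krt4 and Krt6a, and no gene passed the adjusted threshold.

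Proliferation genes fell in the recurrent lines. In the list of DNA replication and E2F targets 31 of 32 members were lower, 20 of them in all 6 lines, with a mean of -0.46 (camera, adjusted p = 1.84e-11; adjusted p = 0.552 with an estimated correlation). Chaf1b (-0.80), Rrm2, a subunit of ribonucleotide reductase (-0.88), Cdc6 (-0.88) and Fen1 (-0.88) had its smallest p. Among G2/M and mitosis genes 33 of 34 were lower, 22 in all 6 lines, with a mean of -0.42 (adjusted p = 1.84e-11; adjusted p = 0.552 with an estimated correlation), including Racgap1 (-0.56), the kinase Aurka (-0.73), Kif23 (-0.67) and Kif2c (-0.79). MYC targets for ribosome biogenesis and growth fell as well, with 34 of 37 lower, 17 in all 6 lines, and a mean of -0.37 (adjusted p = 4.6e-07; adjusted p = 0.676 with an estimated correlation), including Grwd1 (-1.0), Rrp9 (-0.94), Ddx18 (-0.55) and Rrp12 (-1.11). No member of these lists passed on its own. The MYC list stood between -0.71 in AZD1208 2 and -0.01 in vehicle 3 relative to the parental line.

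The PIM kinase list fell (adjusted p = 0.00176; adjusted p = 0.506 with an estimated correlation). Pim1 was 1.77-fold lower (-0.83, SE 0.35; -0.47 as the mean of its probe sets), Pim3 1.7-fold lower (-0.76, SE 0.23) and Pim2 1.16-fold lower (-0.21, SE 0.21), each below the parental value in 6 of 6 lines. For Pim2 the parental value was 8.042, with a technical SD of 0.086 between its arrays. Vehicle 3 (7.962) and AZD1208 2 (7.991) lay less than that SD below it, and the other lines lay further below. Of the 3, 1 passed when adjusted over the list alone (Pim3, adjusted p = 0.0378) and 0 over all genes.

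Androgen receptor targets rose, with 17 of 26 members higher, a mean of 0.44 and a median of 0.11 (adjusted p = 0.00464; adjusted p = 0.506 with an estimated correlation). The members of smallest p were the transcription factor Zbtb16 (0.83), the metalloreductase Steap4 (3.06), the membrane peptidase Mme (2.07) and the amino acid transporter Slc38a4 (2.37), none past the threshold. Luminal prostate genes fell, with 11 of 18 lower and a mean of -0.36 (adjusted p = 0.00469; adjusted p = 0.525 with an estimated correlation), led by Krt19 (-1.52), the prostate stem cell antigen gene Psca (-3.00), Esrp2 (-0.49) and Cldn3 (-0.41, or -0.26 with array quality weights). Krt19 passed when adjusted over the list alone (adjusted p = 0.00395), and no member passed over all genes.

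Glycolysis genes fell, with 12 of 16 lower and a mean of -0.20 (adjusted p = 0.023; adjusted p = 0.648 with an estimated correlation), including Tpi1 (-0.51), Pfkp (-0.76) and Pfkl (-0.83), while the aldolase gene Aldoc was higher (0.99). Genes of cholesterol and fatty acid synthesis fell, with 17 of 23 lower and a mean of -0.16 (adjusted p = 0.0395; adjusted p = 0.746 with an estimated correlation), including Mvk (-0.64), Pmvk (-0.47) and Mvd (-0.36), with Acss2 at 0.29 (0.18 with samples centred on their median). With quantile normalization both calls were lost (adjusted p = 0.0548 and 0.0652), and the cholesterol call was lost without vehicle 1 (0.0563), vehicle 3 (0.14), AZD1208 1 (0.0871) or AZD1208 3 (0.165).

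Fibroblast markers had a mean of 0.62 and a median of 0.02 (adjusted p = 0.283), with Postn at 4.16, Pdgfra at 1.68 and Fbln2 at 1.17, each above the parental value in 6 of 6 lines, and Twist2 at -0.36. None of the 4 passed the threshold. Endothelial markers had a mean of -0.08, myeloid markers 0.04 and lymphocyte markers -0.08 (adjusted p = 0.278, 0.798 and 0.588). In the basal list (mean -0.50, adjusted p = 0.278) Krt6a passed when adjusted over the list alone (adjusted p = 0.013). So did Igfbp5 among senescence-associated secretory genes (0.000467) and Aldh1l2 among ATF4 targets (0.021), with 0 over all genes. Camera called 8 of 32 lists, 1 up and 7 down, and fry called 0 (smallest adjusted p = 0.63). The 24 lists not called had adjusted p between 0.0732 and 0.832.

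**Figure D3:**
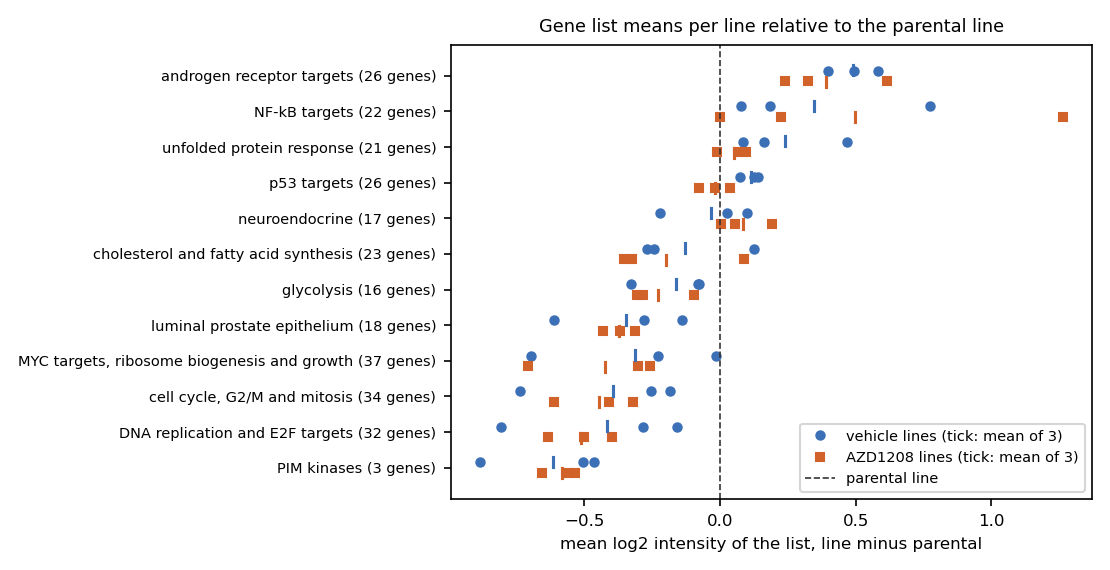
Mean log2 intensity of each gene list in each line minus the parental line (horizontal axis), for the lists called between AZD1208 and vehicle lines or between recurrent lines and the parental line; circles are vehicle lines, squares AZD1208 lines, ticks the mean of 3 lines, and the dashed line the parental level. The DNA replication list lies below the parental level in all 6 lines, between -0.81 and -0.16, and the NF-kB list ranges from 0 in AZD1208 1 to 1.26 in AZD1208 2.

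Each recurrent group was also set against the parental line. In vehicle lines 8 lists were called, 3 up and 5 down. Mitosis genes fell, with all 34 members lower (mean -0.39, adjusted p = 1.02e-09; adjusted p = 0.496 with an estimated correlation). Unfolded protein response genes rose, with 18 of 21 higher (mean 0.24, adjusted p = 0.00626; adjusted p = 0.496 with an estimated correlation), but not when vehicle 1 was left out (adjusted p = 0.191). NRF2 and glutathione genes rose, with 13 of 18 higher (mean 0.29, adjusted p = 0.0342; adjusted p = 0.496 with an estimated correlation), a call lost without vehicle 3 (0.0701), AZD1208 2 (0.0556) or AZD1208 3 (0.0651). In AZD1208 lines 12 lists were called, 5 up and 7 down. DNA replication genes fell, with 31 of 32 lower (mean -0.51, adjusted p = 1.17e-11; adjusted p = 0.686 with an estimated correlation). NF-kB targets rose, with 19 of 22 higher (mean 0.50, adjusted p = 0.0129; adjusted p = 0.686 with an estimated correlation), a call lost without AZD1208 2 (0.625) or AZD1208 3 (0.0691). Without AZD1208 3, 4 of the lists were called. Of single genes 0 passed in either comparison (limma), with 357 and 408 at an unadjusted p under 0.05, where chance gives 776.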

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

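All alternatives but centring of the gene lists were chosen before the data were examined. The count of genes between AZD1208 and vehicle lines was 0 under all 19 alternatives, including the replicate block. For vehicle, AZD1208 and recurrent lines against parental, the parental arrays as 3 separate samples gave 53, 41 and 156 genes in place of 0, because technical spread then counts as spread between samples. Centring samples on their median gave 2 genes for AZD1208 and 2 for recurrent lines against parental, array quality weights gave 2 and 1, and leaving out lines gave 0 to 1 for AZD1208 against parental (1 without vehicle 1). The cause was not tested. With an estimated correlation or fry, 0 lists were called in each comparison. The estimate was 0.547 for MYC targets, but -0.02 for p53 targets and 0.002 for androgen receptor targets, both below the preset 0.01. For p53 and androgen receptor targets a correlation stronger than the preset does not account for the lost calls. Between AZD1208 and vehicle lines, 1 list was called without the filter and 1 with quantile normalization, and 3 to 12 with a line left out (12 without AZD1208 1). Between AZD1208 lines and parental it was 4 to 12 with a line left out (4 without AZD1208 3). With the replicate number as a block 8 lists were called between AZD1208 and vehicle lines against 4 without it. The block was run for that comparison alone, where it kept the 4 calls, added 4 and left the gene count at 0, and beyond the 4 added lists it changed no other call. The cause was not tested for these list counts.

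Of the log2 differences of named genes, 2888 kept their direction and side of the threshold, 30 passed it and 16 turned their sign. Of list calls 247 were kept, 108 lost and 1 turned. For AZD1208 against vehicle, array quality weights turned Tnfaip3 (-0.278), Fbln1 (-0.144), Stat2 (-0.002), Ddit4 (0.001), Pim1 (-0.063) and Pim2 (-0.006), and quantile normalization turned Myc (0.017). The weights also moved Cdkn1a to -0.267, Nfkbie to 0.274, Relb to 0.095, Slpi to 0.547 and Myc to -0.455. As the mean of its probe sets Pim1 was -0.473 in recurrent lines against parental. Centring turned Myc for recurrent lines against parental (-0.023). With a line left out, AZD1208 against vehicle ranged from -0.052 to 0.518 for Stat2, -0.427 to 0.077 for Trp63, -0.078 to 0.389 for Pim1, -0.288 to 0.19 for Myc and -0.006 to 0.367 for Cdh3. Myc in recurrent lines against parental ranged from -0.036 to 0.204, and the adjusted p of NF-kB targets from 4.52e-06 to 0.409, with the direction turned at 0.396. The cause was not tested for any of these. Without detection calls, the array's signal over background sets no limit for dim genes that could be stated here.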

Other observations

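The tests of carried-over host cells in this part were chosen only after the result was seen. Some members of the NF-kB list varied widely from line to line within both groups, and the genes given here were chosen after their values were seen. Saa3, an acute phase protein, was at 6.48 in the parental line, 11.29 in AZD1208 2, 11.13 in vehicle 1, 11.12 in vehicle 2, 8.97 in AZD1208 1, 8.33 in AZD1208 3 and 7.46 in vehicle 3. Among macrophage markers Lyz2 was at 7.10 in vehicle 1, 6.97 in vehicle 2 and 6.42 in AZD1208 2, the 3 lines highest in Saa3, against 4.74 to 5.18 elsewhere, and Cd68 at 7.57, 7.39 and 8.08 against 7.04 to 7.24. Adgre1 was at 6.22 in vehicle 1, 6.54 in vehicle 2 and 5.72 in AZD1208 2, against 5.38 to 5.81, while Csf1r (5.93 to 6.17) and Itgam (5.66 to 5.75) lay below their parental values (6.33 and 5.89) in these 3 lines. Of the macrophage list 11 genes passed the filter on dim genes, and Lyz2 and Itgam were not among them. The mean of these 11 relative to the parental line was -0.03 in vehicle 1, 0.14 in vehicle 2 and 0.11 in AZD1208 2. It was highest in AZD1208 3 (0.18), so the mean of these 11 genes did not follow the 3 lines highest in Saa3. A mean over all members, dim ones included, was not computed, so whether the whole list followed them stays open. No test of macrophages carried over was made. Lcn2, an iron-scavenging protein of the innate response, was at 7.01 in the parental line and between 7.37 (AZD1208 3) and 11.35 (AZD1208 2) in the recurrent lines. The chemokine genes Cxcl1 and Cxcl2 were at 7.16 and 7.63 in the parental line, 8.85 and 9.21 in vehicle 2, and 8.90 and 9.40 in AZD1208 2, with the other lines at 7.02 to 7.30 and 7.39 to 7.97. Sod2, a bright member of the list, lay between 11.38 and 11.93 in the recurrent lines.

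In the list of the ATF4 response 5 of 26 members were higher in all 6 recurrent lines than in the parental line, and 3 were lower in all 6. Of all genes tested 22.6% had all 6 lines on one side. Among the higher ones Slc7a11, the cystine importer, differed by 1.52 (SE 0.37), Nupr1 by 2.27 (SE 1.12) and Ddit3 by 0.64 (SE 0.34) on the log2 scale. The list as a whole had 14 members higher (camera, adjusted p = 0.149, or 0.746 with an estimated correlation). Between AZD1208 and vehicle lines Slc7a11 differed by -0.73 (SE 0.28). In the hypoxia list Ddit4 was 2.18-fold higher in recurrent lines (1.13, SE 0.33) and Bhlhe40 1.81-fold lower (-0.86, SE 0.39). None of these genes passed the adjusted threshold.

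Fewer genes than chance gives had an unadjusted p under 0.05 between AZD1208 and vehicle lines (limma, 0.52% against 5%). If a difference shared by lines of the same replicate number alone accounted for this, the block would bring the share to 5%, and it reached 1.09%. If 1 line alone did, leaving it out would, and the highest share was 2.54%, without vehicle 1. Both shares lay above 0.52%, so a part played by either is not excluded. The real split gave 0 genes, which each of the 10 splits of the 6 lines reaches by construction (10 of 10), so this count cannot speak for or against chance, and the highest other gave 60. The real split called 4 lists, 8 of the 10 splits called 4 or more, whichever lists these were, and the highest other called 11. With 10 splits no share under 0.05 can be reached. The split with 60 genes, picked as the highest of the 10, set vehicle 1, AZD1208 1 and AZD1208 2 against the rest. It may reflect a structure among the lines that the groups do not follow. How many genes the highest of 10 splits calls without such a structure was not computed, so this stays open. Vehicle 1 (38.8), AZD1208 1 (20.5) and AZD1208 2 (44.9) were also the 3 lines highest on the first principal component. Vehicle 2 was at 4.76, vehicle 3 at -8.39 and AZD1208 3 at -17.8. That component comes from the same values and is no separate test of the split. Some splits part all 3 pairs of lines with the same replicate number, as the real one does. In these, 81 (the real one), 148, 188 and 819 genes had an unadjusted p under 0.05 (limma) and 0 genes passed. Splits that part 1 such pair gave 319 to 2215 genes under 0.05. Whether the numbers mark true pairs is not known.

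The DNA replication, mitosis and MYC target lists were lower in recurrent lines. A narrower signal range that lowers all bright genes is argued against by 10000 random lists matched on mean expression: each list's median (-0.43, -0.43 and -0.42) lay at percentile 0.01, the smallest that number can give, with 2.5th percentiles of -0.14, -0.13 and -0.14. After quantile normalization of the deposited values the highest of the 3 means was -0.368, as it was before. The medians of the deposited arrays already lay between 6.22 and 6.36, so this step could change little. It cannot speak for or against the authors' background correction, normalization and summary method, which stay open. These percentiles describe these samples, with 1 parental sample behind them. Androgen in the medium, growth in a castrated mouse and the parental sample itself stay open and were not tested, since the design ties them together.

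Postn, which encodes a matrix protein of fibroblasts, was at 5.36 in the parental line and between 7.86 (vehicle 3) and 12.72 (AZD1208 2) in recurrent lines, and Dpt was at 6.04 in the parental line, 11.25 in vehicle 1 and 10.48 in AZD1208 2, with Pdgfra and Fbln2 also higher. Host fibroblasts carried over would bring their abundant transcripts, yet in AZD1208 2 the median change of the 12 other fibroblast markers was -0.139, with Col1a1 at 7.33 against 7.34 in the parental line and Col3a1 at 6.61 against 6.77, although Pdgfrb was at 9.78 against 6.85, Fbln1 at 8.77 against 7.28 and Dcn at 6.68 against 5.37. Acta2, a smooth muscle actin outside that list, was at 11.87 against 7.78. A host cell type with Pdgfrb and Acta2 but little collagen is not excluded by the fibroblast list. Male host cells of any type would raise Y-linked genes if the MYCCaP cells themselves do not express them. The mean change of these genes in AZD1208 2 was -0.059, with levels of the 6 genes between 3.65 and 6.16 over the lines. Of the 6, 1 passed the filter on dim genes. No sample here shows what signal these probe sets give where the genes are expressed, or whether the MYCCaP cells express them. The Y-linked values therefore cannot decide whether host cells were carried over. A rise of these genes within the tumour cells may remain as a hypothesis beside host cells carried over. It was not tested, and nothing measured here tells the 2 apart. The lines also differ from the parental line in androgen and growth in mice.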
